A study of Mus musculus with 16 samples.

How the data were processed

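Gene expression was measured by sequencing of polyadenylated RNA in 16 mouse libraries. Of these, 6 came from whole pancreata of embryos at embryonic day 16.5 (E16.5), 3 controls and 3 knockouts, and 10 came from hand-picked islets of male mice aged 60 weeks, 5 controls and 5 knockouts. Groups were taken from the genotype and title that the labels give, and each library carried its own animal number. No animal number was shared between groups and litters were not available here, so the libraries were analysed as unpaired.

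RNA was extracted and libraries were made with a Kapa mRNA HyperPrep kit, per the labels' protocols. The deposited tables hold raw read counts per gene, whole numbers with a different total in each library, with no normalisation visible in the values. The submitters' processing notes name Trimmomatic, STAR 2.6.0, HTSeq 0.11.1, edgeR and the mouse build mm10, with no role for each. The annotation version and whether strand was used in counting are not given in the sources used here. Reads from a gene and an overlapping gene on the other strand therefore could not be told apart, which concerns Cdh23 with Vsir, Pdx1 with Plut, Ptf1a with Ptf1aos, Pax6 with Elp4 and Pax6os1, Eng with Fpgs, Rpl18 with Sphk2, Hk1 with Hk1os, Hsp90b1 with 1810014B01Rik, Xist with Tsix, Cldn3 with Wbscr25, Cd81 with R74862, Iqgap2 with F2rl2, Rbpjl with Matn4, Gadd45a with E230016M11Rik, H2-Aa with H2-Eb1 and Notch4, Fabp2 with 4933405D12Rik, and Mylk with 1700119H24Rik and E130310I04Rik. The list of such overlaps is not complete, and 9030617O03Rik also has an uncertain division of reads. Some microRNA and predicted entries span wide regions in the tables and overlap many named genes by position. Ins1 and Ins2, the hemoglobin genes, the ribosomal protein genes and the acinar enzyme families have near-identical copies, so the division of reads among their members is uncertain. Coordinates are those of the deposited tables, which also give a length in kb for each gene, not used here. The tables hold no mitochondrially encoded genes, so a list of these that had been fixed was not tested.

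Total counts ranged from 14866194 to 22699934 in the E16.5 pancreata and from 22595400 to 32385042 in islets. No pair of libraries within a group agreed within sampling noise, the lowest chi-square per degree of freedom being 5.09 in pancreata and 6.52 in islets. Of 24091 genes in each table, 14914 were tested at E16.5 and 14219 in islets after the filterByExpr function with its default settings.

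The main test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 with TMM scaling, fitted within each tissue, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05 on the adjusted p. Fold changes are KO against control on the log2 scale. Standard errors were computed from the fold change and its F statistic, and expression levels are TMM-scaled CPM (counts relative to the scaled library size) computed from the deposited counts, given as mean ± SD. A further model over all 16 libraries tested the interaction of tissue with genotype. The overlap of calls was compared with independent lists by Fisher's exact test, two-sided, per direction. Gene lists fixed in advance were tested with camera of limma 3.58.1 at a preset correlation of 0.01 on log2 CPM with a prior count of 2, for lists with at least 3 measured members, 23 lists at E16.5 and 26 in islets. Each list was also tested with an estimated correlation and with the rotation test fry. The pan-epithelial, sympathetic neuron, adrenal cortex and p53 target lists were added after the data had been seen.

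Genes to be named were fixed by a rule before the data were examined, as were the groups, the tests and most of the other settings tried. The rule took Tff2, up to 8 genes that rose and up to 8 that fell with the largest fold change among those past the threshold with a mean of at least 1 CPM and no overlap between groups, leaving out predicted or clone-named genes, immune receptor segments and pseudogenes. It added up to 3 members of each list with the lowest p among those past the threshold, or the 2 most abundant members where none passed, a fixed panel for each tissue, and Xist, Ddx3y, Kdm5d, Uty and Eif2s3y as checks of sex. If fewer than 3 genes had passed in a direction, the 5 with the lowest p would have been added. Of the genes so named, 62 at E16.5 and 70 in islets are reported. A further 27 and 18 genes were chosen after their values were seen, being members behind small list counts, the remaining called islet genes, Zfp423 at E16.5 and genes of the added lists or of the overlap. A few genes that would have been named are not reported here, though they stayed in every test and list.

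Alternatives covered scaling, low-count filters, DESeq2 1.42.0, limma-voom with quality weights, a robust fit, 1 surrogate variable from sva 3.50.0, covariates for sex, blood and acinar content, a minimum fold of 2, and each replicate left out in turn. Scaling to the pan-epithelial list, DESeq2 without each E16.5 control, and the removal of control 052 and KO 055 from islets or a term for them were chosen after seeing the data. An adipocyte list had too few measured members to be tested.

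The tests were run on simulated counts drawn from the real means, library sizes and dispersions with known changes in a seeded set of genes, in 3 draws. For the E16.5 comparison, on 14810 genes, 51.3% of genes changed 1.5-fold and 80.1% of genes changed 2-fold were recovered, and 6.42% of calls were false. With 1 control left out these shares were 45.7% and 73.7% on 14848 genes. For the islet comparison, on 14155 genes, 76.0% and 92.5% were recovered and 5.57% of calls were false. For the interaction, on 13568 genes, 48.8% and 81.1% were recovered and 8.65% of calls were false. A beta cell identity list lowered 1.5-fold was called in 3 of 3 draws in each tissue, and 1 of 60 unchanged lists was called at E16.5 and 0 of 68 in islets. The simulation drew genes independently, so it does not test how camera behaves when genes vary together.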

Results

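Messenger RNA was sequenced from mice in which Tff2, the gene for the secreted peptide trefoil factor 2, was deleted with a Cre recombinase driven by the promoter of Pdx1, a gene active in the early pancreatic epithelium. Controls carried the floxed Tff2 alleles without Cre. Whole pancreata at E16.5 were compared as 3 controls and 3 KO embryos, and islets from male mice aged 60 weeks as 5 controls and 5 KO animals. The count tables held 14866194 to 22699934 reads per pancreas and 22595400 to 32385042 reads per islet library.

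The first comparison concerned the targeted gene itself, which lies on chromosome 17 from 31141062 to 31144282 (mm10, minus strand). Tff2 fell at E16.5 from 32.2 ± 8.38 CPM (SD, n = 3) in controls to 4.76 ± 4.54 CPM (SD, n = 3) in KO pancreata. The log2 fold change was -2.80 with an SE of 0.535 and an edgeR adjusted p of 0.0297. The KO pancreata had 51, 147 and 27 reads of Tff2 and the controls 848, 406 and 611, and no KO value in CPM reached the lowest control value. Without control 02, 08 or 13 the adjusted p was 0.150, 0.108 and 0.0837, and over all alternatives it ranged from 0.00519 to 0.150 with a fold change below 0 in each. In islets the level was 2.44 ± 1.52 CPM (SD, n = 5) in controls and 0.277 ± 0.221 CPM (SD, n = 5) in KO animals, with every KO value below every control value. The log2 fold change of -3.07 (SE 0.594) had an edgeR adjusted p of 0.0884 and did not pass (0.0101 with DESeq2, and 0.0101 to 0.231 over all alternatives that tested it). The effects in the tissues differed by -0.25 on the log2 scale (interaction adjusted p = 0.920). Which exons were deleted is not given in the sources used here, so remaining reads do not measure remaining function.

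**Figure D1:**
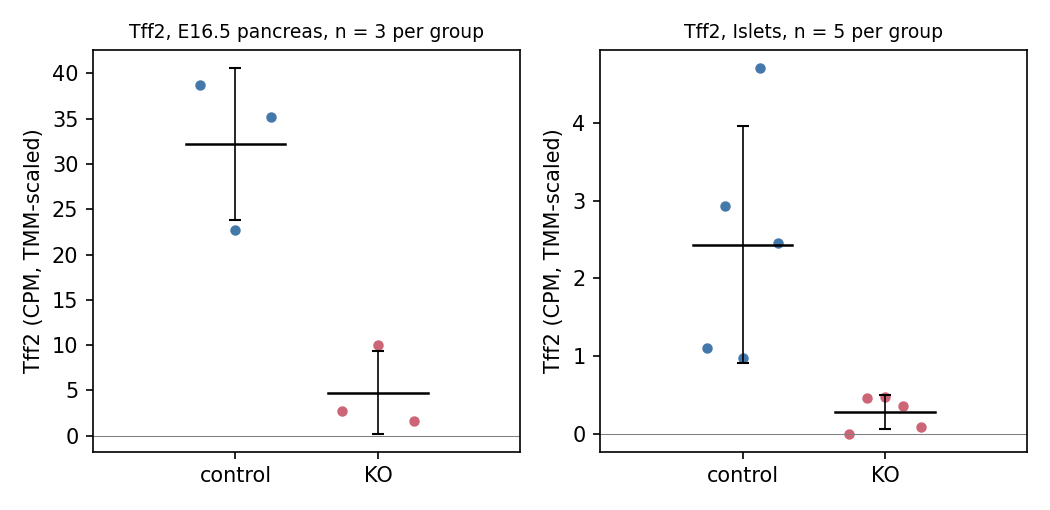
Tff2 level in each library as TMM-scaled CPM, in E16.5 pancreata at left and islets at right. Points are animals, the horizontal bar is the mean and the vertical bar the SD, and KO values lie below control values in both tissues, with highest KO values of 9.96 and 0.478 CPM.

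The comparison of E16.5 pancreata addressed how loss of Tff2 altered gene expression during pancreas development. Islet hormone genes were lower in KO pancreata, and Slc6a2, Dbh and the contractile genes Cnn1 and Myh11 were higher. Ins1 and Ins2, which encode insulin, fell from 357 ± 70.4 to 150 ± 23.5 CPM and from 532 ± 111 to 239 ± 41.7 CPM (SD, n = 3 per group). Slc6a2 and Dbh, the noradrenaline transporter and the enzyme that makes noradrenaline, rose from 0.309 ± 0.222 to 87.7 ± 71.6 CPM and from 0.273 ± 0.118 to 52.4 ± 39.4 CPM. In all, 560 genes rose and 399 fell past an adjusted p of 0.05, and 3791 passed an unadjusted p of 0.05. The values of all 959 called genes did not overlap between groups. Chance gives this for 10% of unselected genes. These genes were selected by the test of the groups, which favours such values, so the lack of overlap is no separate support. The first principal component held 56.4% of the variance and set KO apart from control pancreata. A fold of at least 2 was reached by 300 of those that rose and 17 of those that fell.

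Of 8 islet hormone genes measured, 7 fell and 1 did not pass, and adjusted over the list alone 8 fell. The log2 fold change was -1.25 (SE 0.163) for Ins1, -1.16 for Ins2, -1.14 for Ppy, -1.09 for Pyy, -1.07 for Sst and -0.90 for Ghrl. Gcg, which encodes glucagon, had a log2 fold change of -1.22 with an adjusted p of 0.0619. Of 19 beta cell identity genes, 2 of which are the insulin genes, 12 fell and 17 did adjusted over the list alone. They included G6pc2 at -1.12, Slc2a2, the glucose transporter of beta cells, at -0.87 and the transcription factor Mafa at -1.25. Of 19 endocrine progenitor genes 8 fell, 14 adjusted over the list alone, with Neurog3, the transcription factor that specifies endocrine cells, at -0.65, Insm1 at -0.66 and Pax6 at -0.68. Camera adjusted p was 9.54e-08, 4.12e-11 and 4.72e-08 for these lists. The adjusted p was 0.273, 0.217 and 0.273 with an estimated correlation, and 0.00958, 0.00877 and 0.0151 by fry. Over all lists, 4 of 10 splits of the pancreata gave at least 12 called by camera, the number with the real groups. When scaled to pan-epithelial genes Sst, Neurog3, Insm1 and Pax6 did not pass, at -0.63, -0.22, -0.24 and -0.25 (adjusted p from 0.0555 for Sst to 0.102 for Pax6). Ins1, Ins2, Ppy, Pyy, Ghrl, G6pc2, Slc2a2 and Mafa passed with that scaling, at -0.83, -0.73, -0.70, -0.67, -0.48, -0.70, -0.44 and -0.82. Gcg also passed with it, at -0.82.

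Of 14 duct and trunk genes 5 fell and 1 rose, and adjusted over the list alone 7 fell and 1 rose. Sox9 changed by -0.47 and Wfdc2 by -0.49, while Car2, a carbonic anhydrase, rose by 1.40. Spp1 fell by 0.63 and Anxa4 by 0.33, and these and Car2 were chosen after their values were seen. Under the pan-epithelial scaling described with the epithelial genes Sox9, Wfdc2, Spp1 and Anxa4 did not pass, at -0.03, -0.05, -0.19 and 0.10 (adjusted p = 0.820, 0.666, 0.303 and 0.282). The list was called (camera adjusted p = 0.00096, median -0.29), and the adjusted p was 0.217 with an estimated correlation. None of the 30 acinar enzyme genes passed in edgeR, also adjusted over the list alone, although camera gave an adjusted p of 7.24e-05 for their median of -0.52, which was -0.235 without KO 01 (adjusted p = 0.674 with an estimated correlation). Ctrb1 measured 40230 ± 4178 CPM in controls and 24910 ± 7892 CPM in KO pancreata (SD, n = 3 per group), and Pnliprp1 and Cpa1 had log2 fold changes of -0.50 and -0.49 with adjusted p of 0.158 and 0.109. Acinar enzymes took 12.0% to 14.2% of counts in controls and 6.34% to 11.4% in KO pancreata. Among 8 acinar transcription factors Ptf1a fell by 0.26, and adjusted over the list alone Bhlha15 at -0.38 and Rbpjl at -0.40, chosen after their values were seen, fell as well (camera adjusted p = 0.108). Under pan-epithelial scaling these were at 0.18, 0.07 and 0.04, and Rbpjl was at -0.25 without KO 01. Pdx1 had a log2 fold change of -0.38, 0.05 under pan-epithelial scaling and -0.245 without KO 18, and an adjusted p of 0.133.

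KO pancreata also had lower levels of epithelial genes. Over 15 pan-epithelial genes, a list added after the data had been seen, the median was -0.46 and 10 fell, 14 adjusted over the list alone, among them Krt18 at -0.52 and Cldn3 at -0.64, with Epcam at -0.33 (adjusted p = 0.0946). When scaled to the list itself Epcam was at 0.10, and Krt18 and Cldn3 did not pass, at -0.08 and -0.20 (adjusted p = 0.623 and 0.0597). The camera p was 1.46e-10, and 0.0656 with an estimated correlation. When libraries were scaled to those genes the median of all genes moved to 0.43, and 9797 genes rose and 37 fell, of 14914 tested. A rise past the threshold under that scaling is therefore shared by most genes and is not particular to a gene named with it. With that scaling the medians of the islet hormone, beta cell identity and endocrine progenitor lists stayed below 0, at -0.68, -0.29 and -0.15, while those of the duct and trunk and the acinar enzyme lists were 0.14 and -0.06. The smooth muscle, mesothelium and lymphocyte lists were no longer called, with adjusted p of 0.225, 0.543 and 0.637, and their medians were 1.02, 1.05 and 1.10 against 0.57, 0.61 and 0.66 with TMM scaling.

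Among the genes that rose most, Tfap2b had a log2 fold change of 7.25 (SE 0.958), Tbx20 4.46, Cacng5 4.55 and Slc38a11 4.86, and Slc6a2 and Dbh reached 8.17 (SE 0.975) and 7.61 (SE 0.838). Vwc2l and Insm2 had 1 and 3 counts over the controls and 221 and 246 over the KO pancreata, ratios of 265 (exact 95% interval 47.0 to 10500) and 98.2 (33.2 to 479), intervals that cover counting error only. Of 10 Schwann and enteric neural genes 4 rose and 1 fell, with equal numbers adjusted over the list alone (camera adjusted p = 0.00116, and adjusted p = 0.273 with an estimated correlation). Among them Fabp7 rose by 1.42 and S100b fell by 0.61, both chosen after their values were seen. S100b did not pass under pan-epithelial scaling, at -0.17 (adjusted p = 0.431). Of 10 smooth muscle and pericyte genes 5 rose, 6 adjusted over the list alone, with the contractile genes Cnn1 at 1.75, Myh11 at 1.51 and Actg2 at 1.19, and with Acta2 at 0.59 and Mylk at 0.55, chosen after their values were seen (camera adjusted p = 0.00533, and adjusted p = 0.602 with an estimated correlation). Of 6 mesothelium genes 1 rose, Upk1b at 0.75, and 4 did adjusted over the list alone, adding Wt1 at 0.64, Lrrn4 at 0.60 and Upk3b at 0.57, chosen after their values were seen (camera adjusted p = 0.0088, and adjusted p = 0.602 with an estimated correlation). Under pan-epithelial scaling Wt1, Lrrn4 and Upk3b passed over all genes, at 1.072, 1.039 and 1.011 (adjusted p = 0.00372, 0.00407 and 0.0103), though the list was not called with that scaling.

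**Figure D2:**
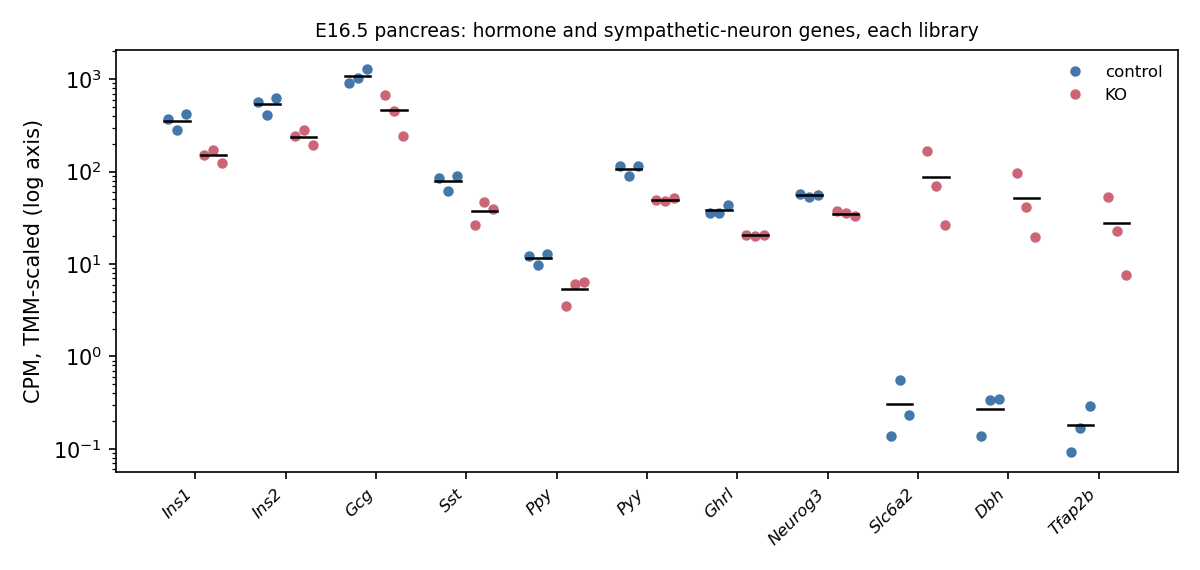
Level of hormone genes, Neurog3 and sympathetic-neuron genes in each E16.5 pancreas, as TMM-scaled CPM on a log axis. Points are embryos and bars are means of 3, and in each of these genes the control and KO values do not overlap.

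Of 12 endothelial genes 2 fell, Eng at -0.58 and Flt1, a receptor of vascular growth factor, at -0.53, and 6 fell adjusted over the list alone, with a list median of -0.41 that was 0.03 under pan-epithelial scaling (camera adjusted p = 0.000786, and adjusted p = 0.602 with an estimated correlation). With that scaling Eng and Flt1 did not pass, at -0.14 and -0.085 (adjusted p = 0.442 and 0.596). Of 24 ribosomal protein genes 3 fell, Rpl14 at -0.31, Rpl18 at -0.33 and Rps18 at -0.28 (0.13, 0.11 and 0.16 under pan-epithelial scaling), and 14 did adjusted over the list alone, with a list median of -0.24 that was 0.20 under pan-epithelial scaling (camera adjusted p = 9.26e-07, and adjusted p = 0.546 with an estimated correlation). None of 22 unfolded protein response genes passed over all genes and 7 fell adjusted over the list alone, with Hspa5 at -0.14 and Hsp90b1 at -0.10 (0.31 and 0.34 under pan-epithelial scaling), and the list median of -0.20 was 0.24 under pan-epithelial scaling and -0.084 without KO 01 (camera adjusted p = 0.000148, and adjusted p = 0.602 with an estimated correlation). None of 6 measured lymphocyte genes passed, also adjusted over the list alone, with Cd3e at -0.14 and Lck at 0.18 (camera adjusted p = 0.0383, and adjusted p = 0.518 with an estimated correlation). Under pan-epithelial scaling Lck passed, at 0.612 (adjusted p = 0.0211), and Cd3e did not, at 0.32 (adjusted p = 0.192). Without control 13 and without KO 18 the lymphocyte list was not called, with camera adjusted p of 0.203 and 0.139.

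Single genes passed in lists that were not called. Lyz2 rose by 0.95 among macrophage and myeloid genes (list adjusted p = 0.0898), Fn1 by 0.53 among fibroblast and matrix genes (0.337) and Hey2 by 0.65 among Notch pathway genes (0.439), while Ier2 fell by 0.35 among immediate early genes (0.601), though its fold change was 0.09 under pan-epithelial scaling. Adjusted over the list alone these lists gave equal counts, except that Mfng at -0.41 (0.03 under pan-epithelial scaling) and Nrarp at -0.47 (-0.036 under that scaling, adjusted p = 0.796), chosen after their values were seen, fell among Notch pathway genes. No erythroid gene passed over all genes, and 3 rose adjusted over the list alone, among them Slc4a1 at 1.57 and Epb42 at 1.05, chosen after their values were seen (camera adjusted p = 0.114). Without KO 01 these were at 0.94 and 0.55. Under pan-epithelial scaling Slc4a1 and Epb42 passed over all genes, at 1.949 and 1.447 (adjusted p = 0.00397 and 0.00547). No member passed among the liver, proliferation, stomach and intestine, spleen stroma and trefoil receptor lists, also adjusted over the list alone, and their camera adjusted p were 0.0779, 0.677, 0.972, 0.861 and 0.854. Albumin, Alb, measured 51.6 ± 42.4 CPM in controls and 247 ± 320 CPM in KO pancreata, and Afp 58.1 ± 29.1 CPM and 246 ± 311 CPM (SD, n = 3 per group). In KO 01 these measured 616 and 605 CPM, and without it their log2 fold changes of 2.27 and 2.09 were 0.30 and 0.22. Under pan-epithelial scaling of all libraries Alb and Afp passed, at 2.568 and 2.411 (adjusted p = 0.0364 and 0.0273). Log2 fold changes were 0.33 for Hbb-bs, 0.23 for Hba-a2, 0.37 for Mki67, 0.12 for Top2a, -1.11 for Fabp2, 0.01 for Lgals4, -0.16 for Madcam1, -0.05 for Nkx2-3, 0.20 for Cxcl12, 0.00 for Ackr3 and 0.23 for Cxcr4, none of them past the threshold, with Madcam1 at 0.28 and Nkx2-3 at 0.39 under pan-epithelial scaling and Nkx2-3 at 0.02 with library totals. With pan-epithelial scaling, which moved the median of all genes to 0.433, Hbb-bs, Hba-a2, Mki67, Top2a, Cxcl12 and Cxcr4 passed. They were then at 0.783, 0.68, 0.793, 0.555, 0.639 and 0.652 (adjusted p from 0.00209 for Mki67 to 0.0327 for Hba-a2). The median and the test differed in sign for the immediate early list, and the median and the mean did for the proliferation and trefoil receptor lists. Xist measured 1.55 CPM and Ddx3y 134 CPM in KO 18, whereas Xist was between 1092 and 1802 CPM and Ddx3y at most 0.173 CPM in the other pancreata.

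By edgeR the E16.5 count fell to 0 without control 02, 4 without control 08 and 0 without control 13, with 2606, 2923 and 3420 genes at an unadjusted p under 0.05, while DESeq2 called 613, 782 and 1224 genes in those sets, and all 959 genes kept their direction in each. Without KO 01, 18 or 19 edgeR called 1035, 857 and 796 genes. A covariate for erythroid genes left 48 genes, 1 surrogate variable gave 2139 and DESeq2 1548, and scaling by library totals changed the split to 779 that rose and 179 that fell.

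The comparison of islets addressed the state of adult islets at 60 weeks of age. A small number of genes differed, 16 that rose and 6 that fell, with 1021 at an unadjusted p under 0.05. Values of all 22 did not overlap between groups, which chance gives for 0.794% of unselected genes. As at E16.5, the selection by the test favours such values, so this is no separate support. Zfp423, a zinc finger transcription factor on chromosome 8 (87661810 to 87959595, mm10, minus strand), rose from 1.23 ± 0.303 to 77.2 ± 42.0 CPM (SD, n = 5 per group), a log2 fold change of 5.99 (SE 0.644, edgeR adjusted p = 0.00268). KO 055 measured 7.93 CPM and the other KO islets 78.3 to 121 CPM, and limma-voom with quality weights gave an adjusted p of 0.297, within a range of 6.92e-21 to 0.297 over all alternatives. Aass, an enzyme of lysine breakdown, rose by 1.46, Cdh23 by 1.35, the tight junction gene Cldn2 by 1.10, Fam212b by 0.71, the kinase gene Sgk1 by 0.52, Ambp by 0.47 and Spry4, an inhibitor of receptor tyrosine kinase signalling, by 0.47. Mlph, a protein that links vesicles to the cytoskeleton (chromosome 1, 90915100 to 90951142, plus strand), fell from 28.7 ± 2.97 to 9.79 ± 4.18 CPM, a log2 fold change of -1.55 (SE 0.210, adjusted p = 0.0183). Ffar2, a receptor of short-chain fatty acids (chromosome 7, 30818357 to 30823775, minus strand), fell from 29.0 ± 2.51 to 17.4 ± 1.50 CPM, a log2 fold change of -0.74 (SE 0.0735, adjusted p = 0.00204). Mctp1 fell by 0.58, Ppp1r10 by 0.54, Tmem229b by 0.28 and the lysosomal mannosidase gene Man2b1 by 0.27. The gene with the lowest p was 9030617O03Rik, chosen after its values were seen, at 0.91 (SE 0.059, adjusted p = 3.18e-05).

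**Figure D3:**
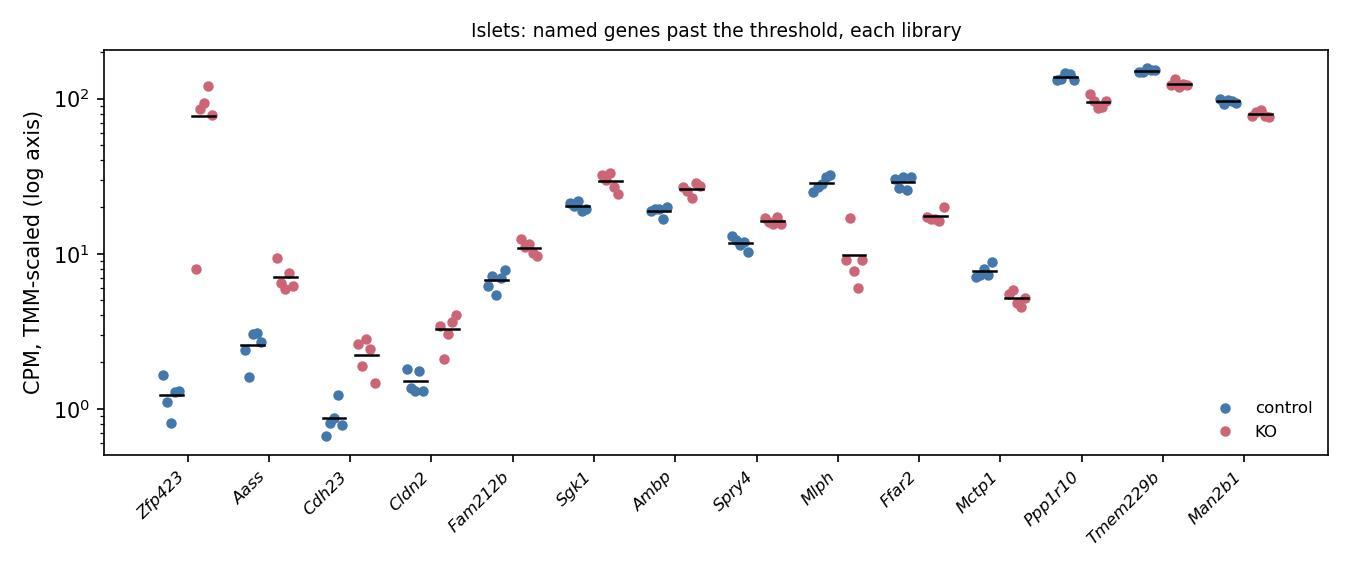
Level of the named genes past the threshold in each islet library, as TMM-scaled CPM on a log axis. Points are animals and bars are means of 5, and the lowest KO point of Zfp423 is KO 055 at 7.93 CPM.

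Genes of islet identity did not pass in islets. Log2 fold changes were -0.04 for Ins1, -0.12 for Ins2, -0.11 for Gcg, -0.03 for Sst, -0.11 for Ppy, -0.01 for Mafa, 0.12 for Pdx1, 0.05 for Nkx6-1, -0.13 for Slc2a2, 0.00 for Ucn3 and -0.13 for Cxcr4, with adjusted p from 0.637 for Pdx1 to 0.997 for Mafa and Ucn3, and Mafa and Ucn3 were at 0.01 and 0.02 when scaled by library totals. None of 8 islet hormone genes passed over all genes and 1 fell adjusted over the list alone, Ghrl at -0.79, chosen after its values were seen (camera adjusted p = 0.0874). The beta cell identity, alpha cell, delta cell, regulated secretion and disallowed gene lists had no members past the threshold, also adjusted over the list alone, and camera adjusted p of 0.237, 0.43, 0.55, 0.601 and 0.903. None of 5 beta cell dedifferentiation genes passed over all genes and 1 rose adjusted over the list alone, Aldh1a3 at 1.58, chosen after its values were seen (camera adjusted p = 0.0874). Among abundant members, Chga had a log2 fold change of 0.00, Scg2 0.04, Ttr -0.11, Rbp4 0.08, Hk1 -0.08, Oat 0.02, Cd81 0.16 and Bambi -0.06.

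The endothelial list was called (camera adjusted p = 0.0109, and adjusted p = 0.855 with an estimated correlation), with 1 of 11 genes past the threshold, Egfl7 at 0.28, and 2 adjusted over the list alone, with Tek at 0.15. Its median of 0.066 was 0.050 without control 826 and 0.005 without KO 055, where camera adjusted p was 0.0513 and 0.176. The ribosomal protein list was called (camera adjusted p = 0.0389, and adjusted p = 0.892 with an estimated correlation) with no gene of 24 past the threshold, also adjusted over the list alone, and a median of 0.032, Rpl4 being at 0.06 and Rpl10 at 0.00. That median was 0.050 without control 052 and 0.051 without KO 122, and 0.013, 0.022, 0.020 and 0.019 without control 826, control 829, KO 803 and KO 812, where the list was not called (camera adjusted p = 0.429, 0.134, 0.163 and 0.318). Of 100 splits of the islet libraries 94 gave at least 2 called lists. Of 11 duct and trunk genes 1 rose, Ambp, and 2 did adjusted over the list alone, with Anxa4 at 0.27 (camera adjusted p = 0.186). Camera adjusted p was 0.137 for proliferation, 0.186 each for erythroid, fibroblast and Schwann genes, 0.25 for trefoil receptors, 0.409 for lymphocyte, 0.43 for macrophage, 0.574 for smooth muscle and for oxidative phosphorylation, 0.694 for acinar enzyme, 0.765 for senescence, 0.899 for interferon and for unfolded protein response, 0.903 for MHC class II, 0.939 for immediate early and 0.983 for Reg family genes. No member of these lists passed over all genes, and adjusted over the list alone 1 rose in the senescence list, Cdkn1a at 0.75, and 1 fell among trefoil receptors, Lingo3 at -0.68. Tek, Anxa4, Cdkn1a and Lingo3 were chosen after their values were seen. The median and the test, or the median and the mean, differed in sign for the acinar enzyme, immediate early, disallowed, senescence, MHC class II and interferon lists. Acinar enzymes took 0.0174% to 0.260% of counts per islet library, and hemoglobin genes 0.00135% to 0.0214%, highest in KO 055.

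**Figure D4:**
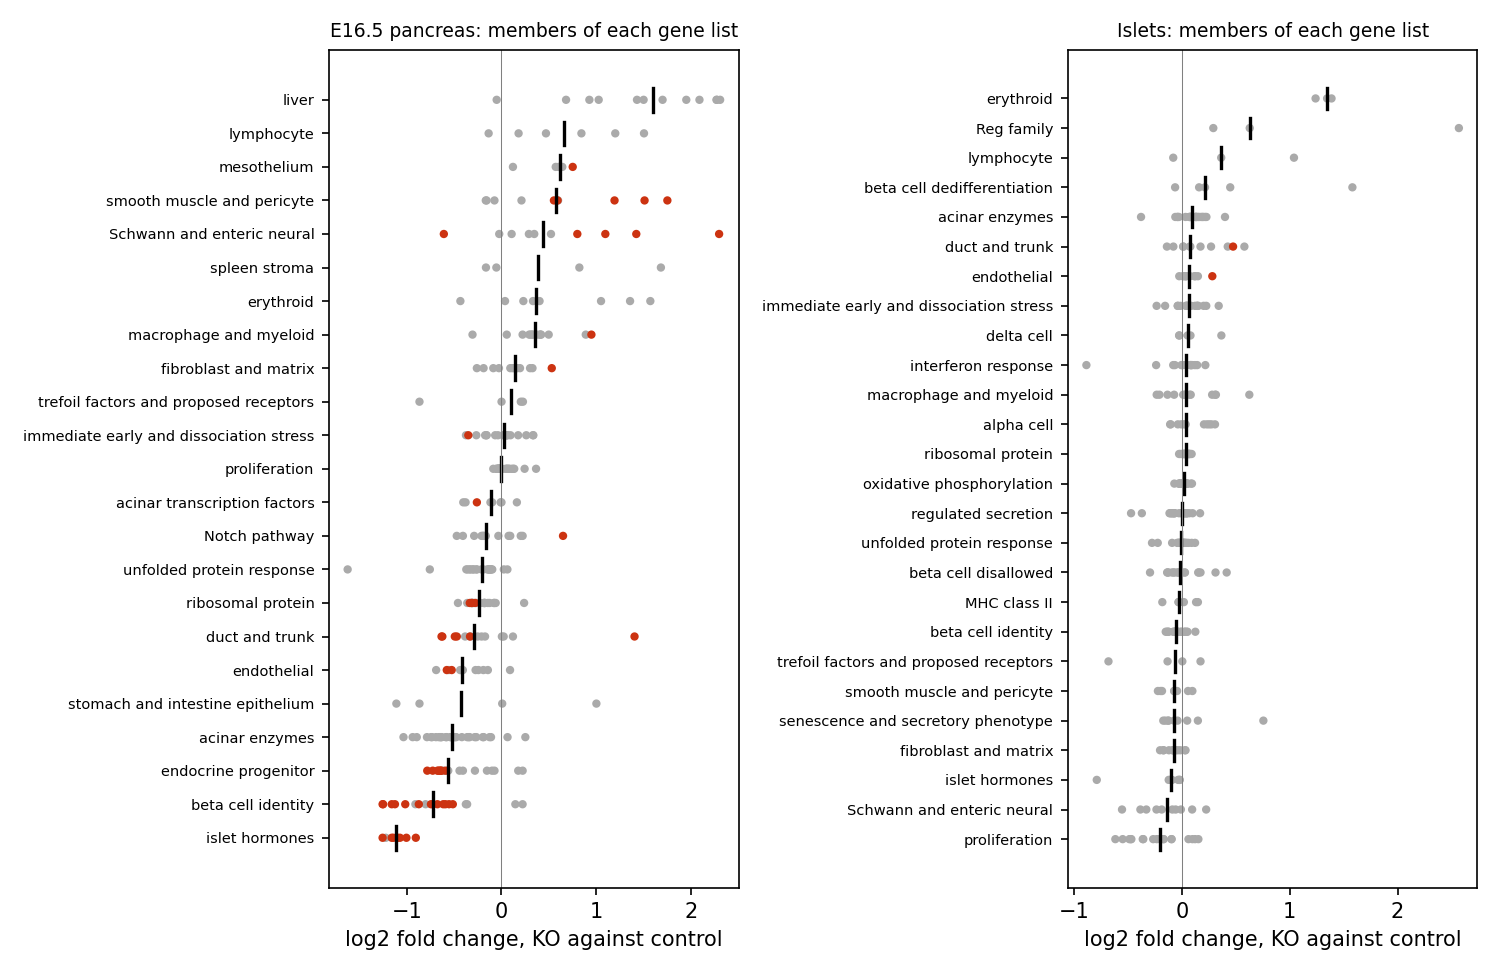
Log2 fold change, KO against control, of each measured member of each gene list, E16.5 pancreata at left and islets at right, with separate horizontal scales. Red points passed an adjusted p of 0.05, grey points did not, black bars are list medians, and islet hormones had a median of -1.12 at E16.5 and -0.10 in islets.

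The islet count fell to 8 without control 052, 8 without control 826, 6 without control 857, 5 without control 858, 8 without KO 803, 6 without KO 812 and 14 without KO 845, and all 22 genes kept their direction in each. DESeq2 called 111 genes, and leaving out both control 052 and KO 055, which stood apart on the second principal component (17.8% of variance), left 8, of which 4 were among the 22, while a term for these libraries gave 33, with all 22 among them.

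Whether the effect of genotype differed between the tissues was tested over all 16 libraries. The effect differed for 1137 of 15823 genes, being higher in islets for 623 and lower for 514. It was higher in islets by 1.23 for Ins1, 1.05 for Ins2, 1.06 for Sst, 1.26 for Mafa and 6.02 for Zfp423, and lower by -8.64 for Dbh and -1.70 for Myh11 on the log2 scale, with adjusted p from 0.00075 for Zfp423 to 0.00698 for Mafa. Without control 02, control 08 or KO 01 at E16.5 the count was 515, 680 and 721, and with the E16.5 groups held 20 of 100 splits of the islet libraries gave at least 1137. Tissue and age cannot be separated in this contrast. Sex goes with them in part, since the islet mice were male and KO 18 was the only male embryo. Any batch difference between the tissues cannot be separated either. Scaling by library totals changed the split to 299 higher and 608 lower. Of 379 genes called lower at E16.5 and 6 in islets among the 13568 tested in both, 2 were shared, Mlph and Ffar2, against 0.168 for independent lists (Fisher's exact test, two-sided, p = 0.0108, adjusted over both directions 0.0217). Of 480 and 16 genes called higher, 0 were shared against 0.566 for independent lists (Fisher's exact p = 1, adjusted 1). 1 gene, Mctp1, was called in opposite directions, rising by 1.00 at E16.5, a value chosen after it was seen. At E16.5 Mlph and Ffar2 had log2 fold changes of -1.12 and -0.96. Under pan-epithelial scaling Mlph did not pass, at -0.67 (adjusted p = 0.0764). Ffar2 passed at -0.53. The shared count was 1 with RLE size factors, library totals or the CPM filter, and 9 with DESeq2, which called 10 in opposite directions.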

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

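The tests of explanations in this part were all chosen only after the results were seen, while the interaction test and the comparison of single libraries with their group were not. Of 154 named genes, 57 had an effect of genotype that differed between islets and E16.5 pancreata by the interaction test, against 1137 of all 15823 genes tested. Many named genes were chosen for a change in these same libraries. That choice favours such a difference, so the larger share is no separate support. On the log2 scale the islet effect was higher by 0.99 for 9030617O03Rik, 1.53 for Aass, 0.82 for Ambp, 0.62 for Anxa4, 2.30 for Cdh23, 1.07 for Cdkn1a, 0.82 for Chga, 1.72 for Cldn2, 0.80 for Cldn3, 0.62 for Eda2r, 0.44 for Egfl7, 0.71 for Eng, 0.35 for Epcam, 0.61 for Fam212b, 0.57 for Flt1, 0.99 for G6pc2, 0.67 for Gadd45a, 1.13 for Gcg, 1.23 for Ins1, 1.05 for Ins2, 0.73 for Insm1, 0.40 for Iqgap2, 0.65 for Kcnab3, 0.64 for Krt18, 1.26 for Mafa, 1.12 for Neurog3, 0.74 for Nkx6-1, 0.63 for Nrarp, 0.45 for Orc6, 0.71 for Pax6, 0.51 for Pdx1, 0.92 for Phlda3, 1.02 for Pyy, 0.79 for Rbp4, 0.35 for Rpl14, 0.36 for Rpl18, 0.31 for Rpl4, 0.28 for Rps18, 0.98 for Scg2, 0.68 for Sgk1, 0.76 for Slc2a2, 0.83 for Spry4, 1.06 for Sst and 6.02 for Zfp423. The difference was -8.64 for Dbh, -9.52 for Ddx3y, -1.46 for Fabp7, -3.97 for Gata3, -5.84 for Insm2, -8.49 for Kdm5d, -1.56 for Mctp1, -1.70 for Myh11, -3.58 for Prph, -4.54 for Slc38a11, -8.41 for Slc6a2, -3.22 for Th and -8.87 for Uty. Ddx3y, Kdm5d and Uty are Y-linked, and their differences follow from KO 18 being the E16.5 pancreas with Y-linked reads. The interaction was not run with pan-epithelial scaling. Under that scaling the E16.5 fold changes of Anxa4, Epcam, Pdx1, Rpl14, Rpl18 and Rps18 changed sign, so their differences may depend on it. The same holds for genes whose E16.5 fold changes moved toward 0 and did not pass under it. These were Krt18 at -0.08, Flt1 at -0.085, Nrarp at -0.036, Eng at -0.14, Cldn3 at -0.20, Neurog3 at -0.22, Insm1 at -0.24, Pax6 at -0.25 and Sst at -0.63. With the E16.5 groups held, every split of the islet libraries gave at least 543 genes, so a difference need not involve the islet groups.

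In 7 of 184 tests a single islet library lay far from its group, the gap to the nearest library as a share of the group's range being above the critical value of Dixon's test for 5 libraries, where chance gives 9.20 such tests. The share was 0.784 for Aldh1a3 and 0.849 for Hspa5, both highest in KO 055, and 0.840 for Zfp423, lowest in KO 055. It was 0.728 for Cd81, lowest in control 052, 0.785 for Hbb-bs and 0.895 for the hemoglobin share of counts, both highest in control 052, and 0.855 for Atp5a1, lowest in control 826.

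Islet hormone genes were lower in KO pancreata at E16.5, with a median log2 fold change of -1.12 and 7 of 8 past the threshold. A lower share of pancreatic epithelium as the whole cause is argued against only weakly. After scaling to pan-epithelial genes the hormone list still had an unadjusted rotation test (fry of limma) p of 0.032 and a median of -0.68. The scaling list was added after the data had been seen and is not restricted to epithelium of the pancreas. Dilution by RNA of other tissue as the whole cause is argued against only weakly. Hormones fell further than acinar transcription factors, by -0.974 (SE 0.206) in mean log2 CPM, with 3 KO pancreata below every control. Against acinar enzymes the gap was smaller, the mean log2 fold change being -1.106 for hormones and -0.48 for enzymes. Whether other tissue also expressed some of these factors was not tested. Dilution as a part of the cause stays open, since the acinar enzyme and pan-epithelial lists also had medians below 0, at -0.52 and -0.46. Embryo sex as the whole cause is argued against by a rotation test p of 0.0056 and a median of -1.23 without KO 18, the male embryo. Fewer endocrine cells, a delay of stage and differences between litters stay open and were not tested, so an effect of the deletion on endocrine development may be one hypothesis among these.

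Sympathetic neuron genes were higher in KO pancreata, 17 of 22 past the threshold with a median log2 fold change of 2.44, in a list written after the leading genes had been seen. The camera p of 2.16e-13 was 0.131 with an estimated correlation, Th, Gata3 and Prph were at 3.68, 3.23 and 3.08, and 3 members are also in the lists fixed earlier. Adrenal cortex carried over is argued against only weakly, by a median of 0.104 for Star and Cyp11a1, which measured 1.26 ± 0.0752 and 3.68 ± 0.988 CPM in controls and 1.72 ± 0.555 and 3.09 ± 1.23 CPM in KO pancreata, only 2 of 7 adrenal cortex genes being measured. Under pan-epithelial scaling Star passed, at 0.881 (adjusted p = 0.0261), and Cyp11a1 was at 0.177 (adjusted p = 0.668). That scaling called 9797 of 14914 genes higher, with a median of 0.433 over all genes, so the rise of Star is not particular to it. A single source present in different amounts cannot be told apart from other differences between the pancreata, since all 17 genes past the threshold were highest in KO 01 and lowest in KO 19 but so were 290 of 543 other genes that rose, in the same order, and KO 01 also had the highest Alb and Afp (616 and 605 CPM) and the lowest acinar share of counts (6.34%). A nearby ganglion or adrenal medulla left in the dissected tissue and denser innervation of KO pancreata stay open.

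Zfp423 was higher in KO islets, with a log2 fold change of 5.99, while at E16.5 it measured 26.8 ± 5.26 CPM in controls and 26.5 ± 5.34 CPM in KO pancreata. More mesenchymal cells in KO islets are argued against by a median of -0.075 over 13 fibroblast and matrix genes. With single libraries left out this median ranged from -0.227 to 0.068. Its SE of 0.020 was taken across the genes and does not measure the spread between animals. A change of the genomic segment around Zfp423 cannot be told apart from an effect of the deletion: Man2b1 and Orc6 were called among 88 genes within 5 Mb (Fisher's exact test, two-sided, p = 0.00737) and among 144 within 10 Mb (p = 0.0189), but no gene was among 18 within 2 Mb (p = 1) or among 23 between 86 and 92 Mb (p = 1). The window of 5 Mb was chosen after both genes had been seen, and adjusted over the 4 windows its p was 0.0295. A transgene or strain segment on chromosome 8 and an effect of Tff2 loss may each account for it, and the value of 7.93 CPM in KO 055 was not explained by a test.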

How the results depend on the processing

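Scaling to the pan-epithelial genes, DESeq2 without single E16.5 controls, and both settings that treat islet control 052 and KO 055 apart were chosen only after the results were seen, as were the genes and lists added to the text. No paired analysis was made, because the groups share no animal numbers and litters were not available here. Unknown links between libraries cannot be excluded, as islet control 052 and KO 055 stood apart together on the second principal component (-21.8 and -22.8). Of 1935 comparisons of 88 named genes at E16.5 with another setting, 1513 kept their direction and their side of the threshold, 290 no longer passed, 69 newly passed and 63 changed direction. For 87 named islet genes these numbers were 1699, 158, 28 and 115 of 2000, for 23 lists at E16.5 216, 26, 13 and 21 of 276, and for 26 islet lists 373, 12, 18 and 38 of 441. For a list the direction is that of its test, which compares it with other genes, and not the sign of its median. Of the 237 changes of direction so counted, 8 concerned a result past the threshold in either setting. Those were Anxa4, Hsp90b1, Ier2, Ptf1a, Rpl14, Rpl18 and Rps18 at E16.5 under pan-epithelial scaling and the islet acinar enzyme list without KO 812 (median 0.373). Not among them are the called duct and trunk, unfolded protein response, ribosomal protein and endothelial lists at E16.5, whose medians crossed 0 under pan-epithelial scaling while their tests kept direction. The cause was not tested unless a sentence gives it.

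The number of genes called at E16.5 was 959, against 1548 with DESeq2, 2139 with 1 surrogate variable, 48 with the erythroid covariate, 9834 with pan-epithelial scaling and 317 with a fold of at least 2, which removes genes by construction. Without control 02, 08 and 13 edgeR called 0, 4 and 0 genes, the range over single libraries left out being 0 to 1035. At an unadjusted p under 0.05 there were 2606, 2923 and 3420 genes, and DESeq2 called 613, 782 and 1224. Tests on simulated counts with 1 control left out recovered 73.7% of genes changed 2-fold and 45.7% of genes changed 1.5-fold. The simulation drew genes independently, without differences that many genes of a library share. It therefore cannot by itself decide whether the smaller groups account for the edgeR counts without 1 control. Leaving out 1 KO pancreas makes the comparison as small, and edgeR then called 1035, 857 and 796 genes without KO 01, 18 and 19. Smaller groups alone are thus argued against as the cause of the counts of 0, 4 and 0. Scaling by library totals gave 779 genes that rose and 179 that fell, and moved the median of all genes to 0.077. Tff2 at E16.5 had a log2 fold change of -2.802 (adjusted p = 0.0675) in the robust fit, -3.418 (0.113) with the erythroid covariate, -2.605 (0.120) with DESeq2 without control 02 and -2.691 (0.0718) with DESeq2 without control 13. It was -2.638, -2.996 and -2.73 in edgeR without control 02, 08 and 13, within -3.887 to -2.391 over single libraries left out. By camera 12 lists were called at E16.5, against 0 with an estimated correlation and 5 with fry, and 12 to 15 over single libraries left out.

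In islets 22 genes were called, against 111 with DESeq2, 5 with a fold of at least 2, 8 without control 052 and KO 055, and 33 with a term for them that kept all 22. The count was 5 to 26 over single libraries left out, with 8 without control 052, 8 without control 826, 6 without control 857, 5 without control 858, 8 without KO 803, 6 without KO 812 and 14 without KO 845. Tff2 in islets had a log2 fold change of -3.124 (adjusted p = 0.0101) with DESeq2, -3.071 (0.0494) with 1 surrogate variable and -3.112 (0.0409) with a term for control 052 and KO 055, and was not tested under the filter on CPM, which left it out. By camera 2 islet lists were called, against 0 with an estimated correlation, 0 with fry, 6 with no filter, 1 with the acinar covariate, 1 without control 052 and KO 055 and 5 with a term for them. The count was 0 to 6 over single libraries left out, with 0 without control 826, 1 without control 829, 4 without KO 055, 4 without KO 812 and 6 without KO 845. The interaction was called for 1137 genes, with 515 to 1186 over single libraries left out, being 515 without control 02, 680 without control 08 and 721 without KO 01 at E16.5. Of genes called in the same direction in both tissues there were 2, against 1 with RLE size factors, 1 with library totals, 1 with the CPM filter and 9 with DESeq2.

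Fold changes of genes that changed sign, and medians of lists whose test changed direction whether or not the median did, were as follows (log2). At E16.5, library totals gave Nkx2-3 0.022 and Zfp423 0.055. At E16.5, no filter gave Ackr3 -0.006 and the list stomach and intestine epithelium 0.001. At E16.5, 1 surrogate variable gave Ackr3 -0.053. At E16.5, Y-linked covariate gave Ackr3 -0.36, Hba-a2 -0.07, Hbb-bs -0.033, Lgals4 -0.23, Xist 0.691, the list macrophage and myeloid -0.019, the list fibroblast and matrix -0.014 and the list trefoil factors and proposed receptors -0.07. At E16.5, erythroid covariate gave Ackr3 -0.017, Cyp11a1 0.022, Hba-a2 -0.059, Madcam1 0.113, Nkx2-3 0.008 and Xist 0.067. At E16.5, pan-epithelial scaling gave Anxa4 0.104, Bhlha15 0.068, Cd3e 0.32, Cyp11a1 0.177, Epcam 0.1, Hsp90b1 0.344, Hspa5 0.308, Ier2 0.085, Madcam1 0.28, Mfng 0.028, Nkx2-3 0.386, Pdx1 0.049, Ptf1a 0.176, Rbpjl 0.044, Rpl14 0.129, Rpl18 0.106, Rps18 0.162, Xist 0.271, Zfp423 0.416, the list erythroid 0.818, the list macrophage and myeloid 0.81, the list fibroblast and matrix 0.582, the list liver 1.926, the list spleen stroma 0.815 and the list trefoil factors and proposed receptors 0.538. At E16.5, DESeq2 without control 02 gave Ackr3 -0.053, Lgals4 -0.148, Nkx2-3 0.028 and Zfp423 0.093. At E16.5, DESeq2 without control 08 gave Ackr3 -0.195, Lgals4 -0.333 and Xist 0.111. At E16.5, DESeq2 without control 13 gave Fabp2 0.577 and Zfp423 0.043. In islets, library totals gave Atp5a1 0.006, Atp5b 0.013, Col3a1 0.012, Hsp90b1 0.021, Hspa5 0.016, Mafa 0.011, Ucn3 0.019 and Uty 0. In islets, no filter gave Chga -0.001 and Rpl10 -0.001. In islets, limma-voom with quality weights gave Chga -0.012, Ctrb1 -0.303, Ctss -0.02, Egr1 -0.434, Fos -0.616, Mafa 0.049, Pnlip -0.357, Reg1 -0.108, Reg2 -0.218 and Rpl10 -0.001. In islets, 1 surrogate variable gave Fos -0.026. In islets, acinar covariate gave Chga 0, Ctss 0, Pnlip -0.013, Rpl10 -0.002 and the list interferon response 0.02. In islets, control 052 and KO 055 left out gave Cd79a 0.004, Ctrb1 -0.01, Ctss -0.059, Ddx3y -0.004, Kdm5d -0.011, Mafa 0.028, Pnlip -0.024, Scg2 -0.036, Ucn3 0.026 and the list beta cell disallowed 0.039. In islets, RLE size factors gave the list Reg family 0.63. In islets, fry gave the list Reg family 0.628. List medians that crossed 0 while the test kept its direction were, at E16.5 with RLE size factors, proliferation 0.005; at E16.5 with Y-linked covariate, proliferation 0.093, immediate early and dissociation stress -0.197 and erythroid -0.005; at E16.5 with pan-epithelial scaling, acinar transcription factors 0.33, duct and trunk 0.143, unfolded protein response 0.24, proliferation 0.431, Notch pathway 0.277, ribosomal protein 0.202 and endothelial 0.026.

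With single libraries left out at E16.5, the ranges for genes that changed sign and for lists whose test changed direction were Ackr3 -0.327 to 0.306, Cyp11a1 -0.604 to 0.004, Fabp2 -2.847 to 0.452, the list fibroblast and matrix -0.002 to 0.229, the list immediate early and dissociation stress -0.179 to 0.122, the list liver 0.131 to 2.552, the list macrophage and myeloid 0.009 to 0.605, the list proliferation -0.104 to 0.08, the list spleen stroma -0.117 to 0.576, the list stomach and intestine epithelium -0.334 to 0.573, Hba-a2 -0.058 to 0.423, Hbb-bs -0.017 to 0.55, Lgals4 -0.334 to 0.695, Madcam1 -0.368 to 0.018, Nkx2-3 -0.13 to 0.051, Xist -0.56 to 0.454 and Zfp423 -0.193 to 0.088. List medians that crossed 0 with no change of direction in the test ranged as follows, the list trefoil factors and proposed receptors -0.053 to 0.283.

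In islets these ranges were Atp5b -0.034 to 0.012, Bambi -0.176 to 0.021, Cd74 -0.086 to 0.022, Cd79a -0.249 to 0.027, Chga -0.017 to 0.023, Col3a1 -0.236 to 0.152, Ctrb1 -0.231 to 0.344, Ctss -0.037 to 0.076, Ddx3y -0.009 to 0.06, Egr1 -0.842 to 1.193, Eif2s3y -0.005 to 0.067, Fos -1.009 to 1.213, the list acinar enzymes -0.24 to 0.373, the list beta cell disallowed -0.112 to 0.042, the list delta cell -0.009 to 0.079, the list fibroblast and matrix -0.227 to 0.068, the list immediate early and dissociation stress -0.757 to 0.911, the list interferon response -0.052 to 0.11, the list MHC class II -0.061 to 0.03, the list oxidative phosphorylation -0.011 to 0.027, the list Reg family -0.188 to 1.107, the list smooth muscle and pericyte -0.152 to -0.03, the list unfolded protein response -0.045 to 0.047, H2-Aa -0.061 to 0.028, Hsp90b1 -0.039 to 0.046, Hspa5 -0.139 to 0.05, Ins1 -0.078 to 0.016, Kdm5d -0.027 to 0.076, Mafa -0.072 to 0.083, Mdm2 -0.057 to 0.007, Oat -0.061 to 0.086, Pnlip -0.36 to 0.372, Ppy -0.441 to 0.076, Reg1 -0.087 to 0.594, Reg2 -0.893 to 2.884, Rpl10 -0.021 to 0.023, Scg2 -0.046 to 0.091, Sst -0.077 to 0.019 and Ucn3 -0.021 to 0.031. Here such medians were the list alpha cell -0.065 to 0.182, the list macrophage and myeloid -0.006 to 0.079 and the list trefoil factors and proposed receptors -0.103 to 0.016.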

Other observations

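The p53 target list and the counts over other splits of the samples were chosen only after the results were seen. Among the islet genes past the threshold and not yet described, Iqgap2, a scaffold protein gene, had a log2 fold change of 0.44, Kcnab3 0.46, Trpm2, a cation channel gene, 0.38, Orc6 0.38, Tnfsf10 0.29 and Cc2d2a 0.26, all chosen after their values were seen. Near Tff2 itself, 11 of 223 genes tested within 5 Mb were called at E16.5 and 1 of 224 in islets (Fisher's exact test, two-sided, p = 0.411 and 0.295).

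A hypothesis is that p53 activity was higher in KO islets. Of 22 measured p53 target genes none passed over all genes by edgeR, and adjusted over the list alone 5 rose, Phlda3 at 0.82, Eda2r at 0.77, Cdkn1a at 0.75, Gadd45a at 0.41 and Ccng1 at 0.34, while Mdm2 was at -0.02. The list median was 0.09, with a camera p of 6.55e-07, of 0.0125 with an estimated correlation, and a rotation test p of 0.00394. The list was written after Cdkn1a had been seen, and Cre recombinase alone may raise these genes, which cannot be told apart from the deletion because no group carried Cre with intact Tff2.

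For the E16.5 genes the splits of 6 libraries are too few, at 10, for a share under 0.05, the real split giving 959 genes in 1 split and the highest other 0. For the E16.5 lists 4 of these 10 splits gave at least 12, the number in the real split, and the highest other gave 14. Chance therefore cannot be excluded for the number of E16.5 lists. For the islet genes 1 of 100 splits, the real one, gave as many as 22 and the highest other gave 2. A chance division of the libraries is argued against for that count, though 1 of 100 is the smallest share these splits could give. The splits do not separate the deletion from other differences that follow the groups. Chance cannot be excluded for the islet lists, where 94 of 100 splits gave at least 2 and the highest other gave 15. For the interaction 4 of 100 splits of both tissues gave at least 1137 genes, the highest other giving 1536, and splits with other E16.5 groups gave at most 3. With the E16.5 groups held, 100 splits of the islet libraries gave at least 543 genes and 20 of them at least 1137, the highest other giving 1631, so chance cannot be excluded for the part of the islet groups in this count. For the genes shared between tissues 1 of those 100 splits gave 2 and the highest other 0, but among them only the real split called at least 2 islet genes, so this decides nothing.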
